A study of Mus musculus with 24 samples.

How the data were processed

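RNA from the brains of 12 mice was sequenced, 6 of the inbred strain CAST/EiJ and 6 of WSB/EiJ. Each animal was sequenced on 2 lanes, numbered 5 and 6, and has a file for each, which makes 24 files. The labels give tissue, strain, animal, lane and library index, and give no sex, age, treatment, dissection or batch. All CAST libraries come before all WSB libraries in the order of the indexes, so this order cannot be told apart from strain. The submitters' processing notes name cutadapt, TopHat2 2.1.1, HTSeq and DESeq2, without roles or order. The genome build, the annotation, the read length and the strand setting are not given in the sources used here.

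The deposited values are whole-number counts of reads per gene, not normalized, in a file with no header that lists an Ensembl gene identifier, its class and its count. Each file lists 53465 genes and 5 counters that name no gene, and these counters were kept out of library sizes and tests. Over the 12 animals, 62.9% to 68.0% of all counted alignments fell in genes, 4.04% to 4.95% in no feature and 11.1% to 16.5% in more than 1 feature. The counter for alignments that were not unique held 15.6% to 17.5%. Of the identifiers, 53360 are in GENCODE M21 (mouse genome GRCm38), which was used for symbols and coordinates here; the build the authors used may be another. Where several identifiers share a symbol, it was given to the identifier with most reads.

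The way reads were assigned to genes limits what these counts can show. In GENCODE M21, 867 protein-coding genes have their whole body inside other genes of the files although at least 90% of their exon bases lie outside other exons. Of these, 860 are listed at 0 reads in all 12 animals, against 2274 of 20712 protein-coding genes whose body is not inside others. Among the 558 of them that overlap genes of the opposite strand only, 553 are listed at 0. Assignment of reads to whole gene bodies, introns included and without regard to strand, would give these values. Of the genes on the lists used below, Gfap, P2ry12, Tubb3, Nefl, B2m, Hif1a, Cav1, Myd88 and Xist are listed at 0 in every animal, so nothing is said of their expression. All 37 genes of the mitochondrial genome are listed at 0 as well. Reads of overlapping and antisense genes cannot be told apart in these counts, and a count may include intronic reads.

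The lane files of each animal were summed, because they hold repeat sequencing of a library and are not replicates. Over genes with at least 20 reads in both lanes together, the chi-square of lane 5 against lane 6 divided by its degrees of freedom was 1.09 to 1.40, and its median was 1.12. The same ratio between different animals of a strain, on lane 5, was 3.53 to 84.6. The 12 sums are treated as separate animals, as their labels number them.

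Strains were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersion, TMM scaling and the default expression filter by strain, which left 18425 genes. Fold changes are CAST over WSB. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are TMM-scaled. Gene lists were tested with camera (preset correlation 0.01, then an estimated correlation) and fry from limma 3.58.1. There were 43 lists of cell type, brain region, pathway and sample condition genes, of which 42 had at least 3 tested members. Strain-restricted genes had at least 10 reads in every animal of a strain and 0 in every animal of the other, and folds for them use a floor of 3 reads over the 6 animals of the low strain. Principal components used log2 CPM with a prior count of 2. Comparisons of a single library measure used exact two-sided permutation of the strain labels.

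Named genes followed a rule fixed, with the lists and the alternatives, before the data were examined. It took the 8 largest fold changes in each direction among called genes with mean log2 CPM of at least 1, separate CPM ranges of the strains and an established symbol; the 4 smallest p values in each direction; up to 3 called members of each list with the smallest p, or the most abundant member of a list with none; and the 3 most abundant strain-restricted genes with an established symbol in each direction, of which CAST had none. Other genes in the text were chosen after their values were seen, and are said to be.

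The share of each gene's transcript 32-mers that also occur in transcripts of another gene was computed from GENCODE M21 as a measure of shared sequence. The test was tried on simulated data with the real means and library sizes, in which 200 genes were changed. These were drawn from the more strongly expressed genes only, so recovery of weakly expressed genes was not tried. For this comparison, with 18244 genes in the step, it recovered 73.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold. The 11 false calls made 5.88% of its calls. A simulated list of 15 genes raised 1.5-fold had a camera p of 1.07e-31 and a fry p of 4.21e-12, and an unchanged list of 15 had a camera p of 0.330 and a fry p of 0.0648. Few genes were changed there and genes varied independently, whereas 7866 genes were called between the strains. The simulation thus does not show how often the list tests call lists in the real data.

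The alternatives were DESeq2 1.42.0, limma voom, other scalings and filters, each lane alone, all 24 files as samples, each animal left out in turn, sex chromosome genes left out, the top 20 and mitochondrial genes left out, and other thresholds. Alternatives added after seeing the data left out CAST_142 and WSB_100 together, or kept only protein-coding genes or genes with their own sequence and body.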

Results

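The data are gene-level read counts from the brains of 12 mice of the wild-derived inbred strains CAST/EiJ and WSB/EiJ, with 6 animals in each. CAST/EiJ descends from Mus musculus castaneus and WSB/EiJ from Mus musculus domesticus. The study asked which genes are expressed differently between strains whose infarcts differ in size after occlusion of the middle cerebral artery, a model of ischemic stroke. The labels name no surgery or treatment for these animals. Reads in genes numbered 42852743 ± 3324750 per CAST animal and 39959790 ± 4353590 per WSB animal (SD, n = 6 each), with a range of 32982569 to 46513232. This difference did not exceed the spread between animals (exact permutation p = 0.229). The share of alignments that were not unique was 15.8% ± 0.195 in CAST and 17.2% ± 0.177 in WSB (SD, n = 6 each; exact permutation p = 0.0022, adjusted p = 0.0152 over 7 library measures), the smallest p these group sizes allow.

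Strain was the main axis of variation. The first principal component held 71.1% of the variance and separated all 6 CAST animals from all 6 WSB animals. The second held 10.1% and set CAST_142 apart from every other animal.

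**Figure D1:**
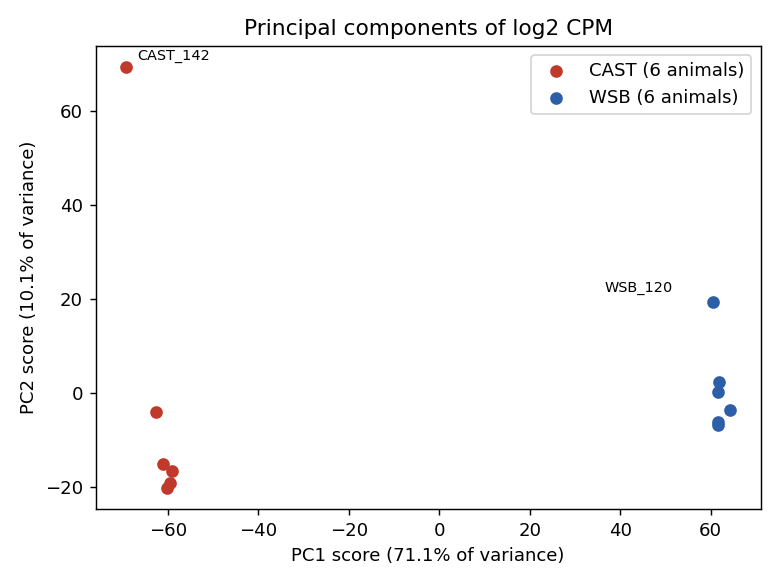
Scores of the 12 animals on the first and second principal components of log2 CPM (arbitrary units; red, CAST; blue, WSB). The strains separate along the first component, with 71.1% of the variance, and CAST_142 stands alone at the top of the second, with 10.1%.

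CAST_142 had high levels of genes of cerebellar neurons and low levels of striatal genes. Cbln3, a secreted synaptic protein of cerebellar granule cells, was at 344 CPM in CAST_142 and at most 11.9 CPM in the other 11 animals. Gabra6, the granule cell GABA-A receptor subunit, was at 333 CPM and Drd2, a dopamine receptor of the striatum, at 4.13 CPM in the same library; these genes were chosen after their values were seen. WSB_100 stood apart with Doc2g (13.8 CPM, against at most 2.11 CPM in other WSB animals), a gene of olfactory bulb mitral and tufted cells. Doc2g shares 57.3% of its sampled 32-mers with other genes, and only 32.2% of its body lies outside other genes. Of 6 tested cerebellar markers, 3 were called higher in CAST, namely Cbln3, Ppp1r17 and Il16 (4 adjusted over the list alone), and with CAST_142 and WSB_100 left out none of the 6 was called. No striatal marker of 11 was called, and Pde10a, the most abundant of them, was at 522 ± 194 CPM in CAST and 561 ± 71.6 CPM in WSB (SD, n = 6 each).

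**Figure D2:**
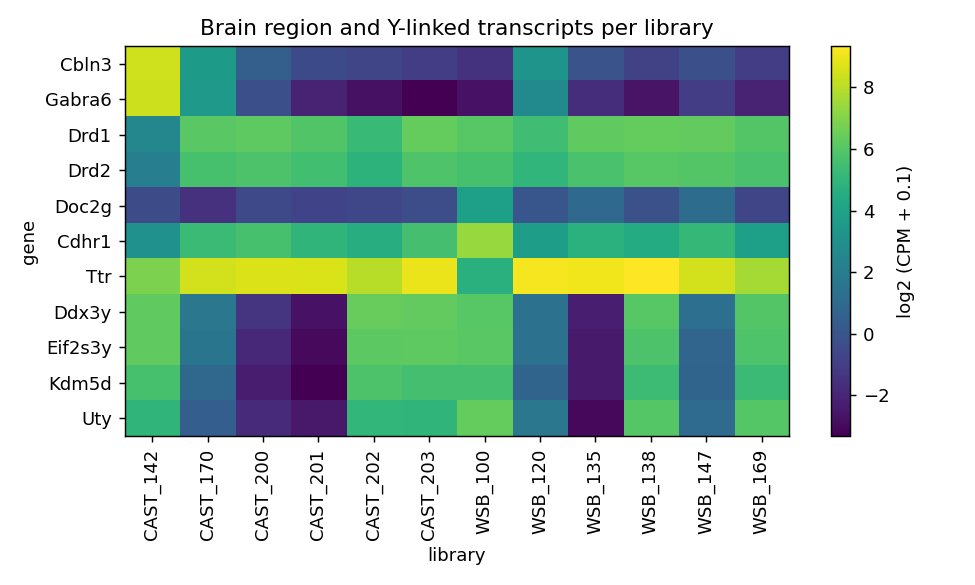
Levels of genes of cerebellum (Cbln3, Gabra6), striatum (Drd1, Drd2), olfactory bulb (Doc2g, Cdhr1), choroid plexus (Ttr) and the Y chromosome (Ddx3y, Eif2s3y, Kdm5d, Uty) in each library, as log2 (CPM + 0.1) on a colour scale. CAST_142 holds Cbln3 at 344 CPM and Drd2 at 4.13 CPM, and the Y-linked genes fall into high, low and very low libraries within both strains.

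Read counts differed between the strains at 7866 of 18425 tested genes (42.7%; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these called genes, 3966 were higher and 3900 lower in CAST. At 2249 of them the difference was at least 2-fold, 1161 higher and 1088 lower. The CPM ranges of the strains did not overlap for 4995 of the 18425 tested genes, where chance gives 0.216% of genes. Of these 4995, 4977 were called. With CAST_142 and WSB_100 left out, 8624 genes were called. Most called differences in protein-coding genes were under 2-fold. Of 14939 tested protein-coding genes, 5868 were called and 1114 (7.46% of those tested) were called with at least 2-fold. Pseudogenes reached that size far more often, at 414 of 1024 tested (40.4%; Fisher's exact test, odds ratio 5.76, adjusted p = 1.29e-124). So did long noncoding genes, at 650 of 2200 tested (29.5%). Those called at any size were 696 pseudogenes and 1170 long noncoding genes, so these shares reflect both frequency and size. Genes are not independent replicates in these tests. The median size of the called log2 fold changes was 0.566. Reads of the strains may align unequally to the reference, and how far this adds to the calls was not tested.

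**Figure D3:**
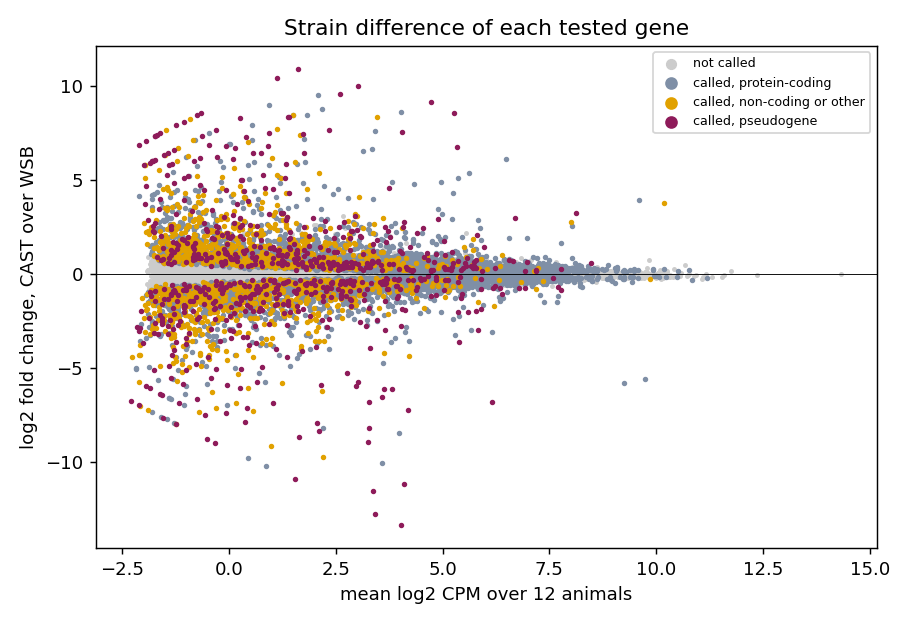
Log2 fold change of CAST over WSB against mean log2 CPM for the 18425 tested genes, with called genes coloured by class. The 7866 called genes lie on both sides of 0, and called pseudogenes lie far from it more often than called protein-coding genes.

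Among genes with an established symbol and a mean log2 CPM of at least 1, several with higher counts in CAST had almost no reads in WSB; unnamed pseudogenes had larger differences in both directions. Ly6c1, an endothelial and leukocyte surface protein (chromosome 15, 75044018 to 75048830, GRCm38), was at 8.38 ± 0.808 CPM in CAST and 0.00784 ± 0.0122 CPM in WSB (SD, n = 6 each), a log2 difference of 9.53 ± 0.27 (SE; adjusted p = 1.17e-11 by edgeR). Rubcnl, which takes part in autophagosome maturation, was at 176 ± 27.4 against 2.49 ± 0.509 CPM. Kcnmb3, an accessory subunit of large-conductance potassium channels, was at 19.99 ± 4.75 against 0.1999 ± 0.0931 CPM. Sult3a1, a sulfotransferase, Cyp2b13, a cytochrome P450, the zinc finger genes Zfp937 and Zfp738, and Trim43b completed the largest differences within these limits, with log2 changes of 5.99 to 8.82. Ap2m1, a subunit of the clathrin adaptor, was at 199 ± 11.9 against 53.2 ± 2.11 CPM, and the ribosomal protein genes Rpl37a and Rpl37 were 4.32 and 3.48 higher on the log2 scale. Ly6c1, Trim43b, Ap2m1, Rpl37a, Zfp937, Cyp2b13 and Rpl37 share 36.0% to 58.0% of their sampled 32-mers with other genes, so their counts are uncertain.

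Under the same limits, lower counts in CAST were led by Fam213b, a prostaglandin F synthase, at 0.0182 ± 0.0250 CPM in CAST and 23.7 ± 2.04 CPM in WSB (SD, n = 6 each), a log2 difference of -10.05 ± 0.26 (SE; adjusted p = 3.98e-12 by edgeR). Cwc22, a splicing factor that loads the exon junction complex (chromosome 2, 77881159 to 77946375, GRCm38), had the smallest p of all genes named here: 1203 ± 78.6 CPM in WSB and 21.7 ± 1.12 CPM in CAST, or 55.6-fold (adjusted p = 3.23e-15 by edgeR). Pon2, a lactonase with antioxidant activity, was at 27.1 ± 1.94 CPM in WSB and 2.53 ± 0.253 CPM in CAST, and Tmsb10, an actin-binding thymosin, at 31.4 ± 1.51 and 3.64 ± 0.308 CPM. Krt20, a keratin, Dnajc5b, Gpr55, a lipid-sensing receptor, Aldh3b2 and Vmn2r87, a vomeronasal receptor, were lower in CAST by log2 changes of -4.01 to -8.23. Vmn2r87, Tmsb10, Cwc22, Aldh3b2 and Dnajc5b share 20% to 54.7% of their sampled 32-mers with other genes, and copy number in either strain was not analysed here.

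Tmtc2 also had a large difference, at 1678 ± 858 CPM in WSB and 34.7 ± 8.87 CPM in CAST (SD, n = 6 each), but its level in WSB ranged from 644 to 2937 CPM. Over the 6 WSB libraries it rose with CT010467.1, a ribosomal-RNA-type gene that took 0.756% to 3.19% of gene reads in them (Pearson r = 0.92, exact permutation p = 0.0097, adjusted p = 0.0156; Spearman rho = 0.94, exact permutation p = 0.0167, adjusted p = 0.0222; 8 relations of 4 genes computed). Without WSB_169 and WSB_147, the farthest from the median of CT010467.1, r was 0.99. Over the 6 CAST libraries r was 0.18 (exact permutation p = 0.693, adjusted p = 0.693) and rho 0.37 (exact permutation p = 0.497, adjusted p = 0.497), and r was -0.31 without CAST_201 and CAST_200.

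**Figure D4:**
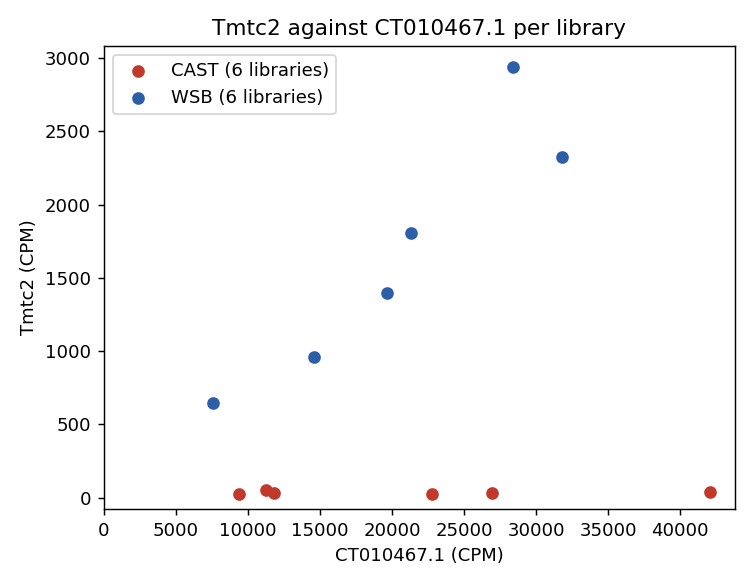
Tmtc2 (CPM) against CT010467.1 (CPM) in each library (red, CAST; blue, WSB). In the 6 WSB libraries Tmtc2 lies between 644 and 2937 CPM and rises with CT010467.1, and in the 6 CAST libraries it stays between 26.4 and 49.3 CPM.

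Reads of 35 genes were restricted to a strain. The 16 genes with reads in CAST alone comprised 14 pseudogenes and no protein-coding gene. Several of the 16, among them Gm9231, Gm48016 and Gm9315, lie in a stretch of chromosome 12 (18364462 to 24383161), so they may not be independent. Without WSB_100 the genes with reads in CAST alone numbered 27, against 23 in WSB alone. Of the 8 genes named for the largest increases in CAST, WSB_100 held the highest WSB level of all but Cyp2b13. Sult3a1 was at 0.333 CPM in it, Kcnmb3 at 0.333 CPM and Trim43b at 0.230 CPM. For Ly6c1 and Zfp937 this rests on few reads (2 and 4 over all WSB animals). For Zfp738 the next WSB library was near (0.154 and 0.152 CPM). In the order of the library indexes WSB_100 directly follows CAST_203. Mixing of reads between libraries was not tested, so the count of 16 is uncertain. The 19 genes with reads in WSB alone comprised 9 pseudogenes and 6 protein-coding genes. The vomeronasal receptors Vmn2r84 and Vmn2r85 were at 3.56 ± 0.813 and 2.68 ± 0.568 CPM in WSB (SD, n = 6), at least 309-fold and at least 230-fold higher than in CAST, and Vmn2r85 shares 21.3% of its sampled 32-mers with other genes. Iigp1, an interferon-inducible GTPase, was at 0.740 ± 0.145 CPM in WSB, at least 63.7-fold higher. Reads can also be missing where a strain's sequence differs from the reference. Such floors cover counting error only.

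Interferon-stimulated genes were called lower in CAST more often than higher. Of 27 tested members, 13 were lower, 3 were higher and 11 were not called; adjusted over the list alone the counts were 13 and 3. Rtp4, a chaperone induced by interferon, was at 0.743 ± 0.132 CPM in CAST and 3.53 ± 0.276 CPM in WSB (SD, n = 6 each), and Oas1a, a sensor of double-stranded RNA, at 0.167 ± 0.0247 and 1.01 ± 0.155 CPM. Ifit3 was at 0.692 ± 0.262 and 4.88 ± 0.673 CPM. The 3 higher members were Gbp3, Mx1 and Mx2, antiviral GTPases, which were named after their values were seen. Fry found the list lower in CAST on balance (adjusted p = 7.61e-08). Camera, which compares the list with other genes, did not pass (adjusted p = 0.151, and adjusted p = 0.355 with an estimated correlation), except with no filter on low counts (adjusted p = 0.00545). Oas1a and Ifit3 share 68.7% and 61.3% of their sampled 32-mers with other genes, and only 57.6% of the Rtp4 body lies outside other genes. With CAST_142 and WSB_100 left out, 14 members were lower and 3 higher.

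**Figure D5:**
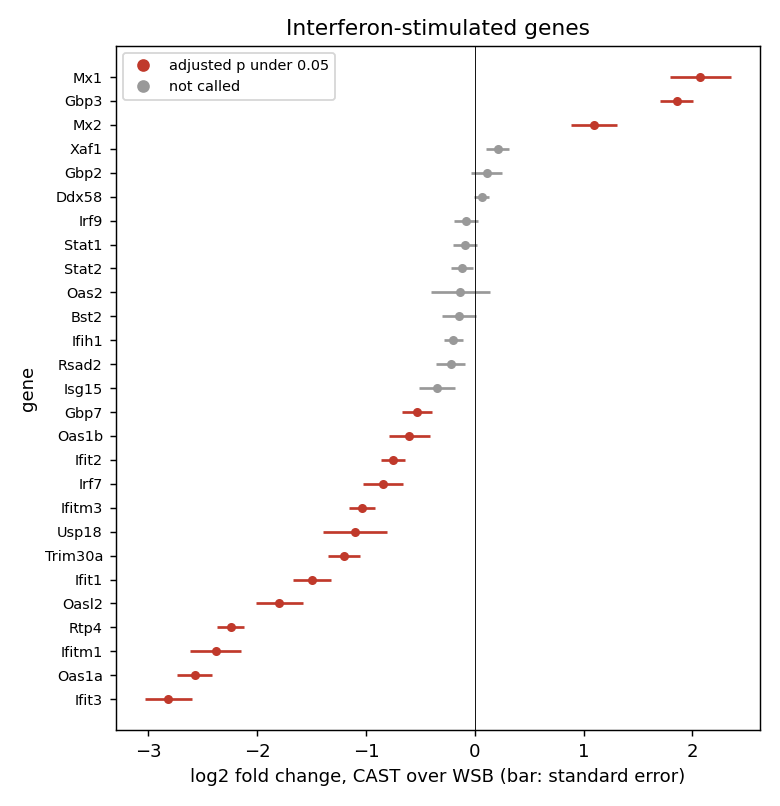
Log2 fold change of CAST over WSB for the 27 tested interferon-stimulated genes, with bars for the standard error. Of the called members (red), 13 lie below 0 and 3 above it.

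Of 19 tested cytokine and inflammatory signalling genes, 10 were higher and 2 lower in CAST, the same counts as adjusted over the list alone, and fry found the list higher on balance (adjusted p = 9.74e-05; camera adjusted p = 0.964, and adjusted p = 0.999 with an estimated correlation). Tlr4, the receptor for lipopolysaccharide, was at 7.84 ± 0.711 CPM in CAST and 2.12 ± 0.478 CPM in WSB (SD, n = 6 each), and Pycard, the inflammasome adaptor, at 2.71 ± 0.396 and 1.26 ± 0.145 CPM. Il18 went down, at 6.998 ± 0.768 and 18.7 ± 0.699 CPM. Of 12 tested microglial markers, Aif1, C1qa and 3 others were lower and C1qc alone was higher (fry adjusted p = 0.254). Of 7 leukocyte markers, S100a9 and Mrc1 were higher and none was lower (fry adjusted p = 0.254). Of 7 erythroid genes 3 were higher and 1 lower (fry adjusted p = 0.573). Hba-a1, a hemoglobin gene that shares 80% of its sampled 32-mers with other genes, was at 34.1 ± 18.2 and 18.1 ± 5.92 CPM, and its call was lost without CAST_170 (adjusted p = 0.0739), CAST_200, WSB_100, WSB_135 or WSB_138. With CAST_142 and WSB_100 left out, 3 leukocyte markers were higher (fry adjusted p = 0.0180; camera adjusted p = 0.965, and adjusted p = 0.983 with an estimated correlation).

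Of 10 tested mural cell markers, 6 were lower in CAST and none higher (fry adjusted p = 9.74e-05; camera adjusted p = 0.372, and adjusted p = 0.999 with an estimated correlation). With CAST_142 and WSB_100 left out, 5 were lower and none higher (fry adjusted p = 8.30e-05). Rgs5, a pericyte regulator of G protein signalling, was at 45.8 ± 4.03 CPM in CAST and 117 ± 9.20 CPM in WSB (SD, n = 6 each), Vtn, vitronectin, at 22.3 ± 3.57 and 41.2 ± 2.69 CPM, and Abcc9, a potassium channel subunit, at 10.1 ± 0.774 and 15.01 ± 1.45 CPM. Blood-brain barrier genes were lower at 6 and higher at 1 of 18 (6 and 2 adjusted over the list alone; fry adjusted p = 0.0130; camera adjusted p = 0.964, and adjusted p = 0.999 with an estimated correlation), with Tfrc, the transferrin receptor, at 75.1 ± 6.43 and 109 ± 8.67 CPM. Endothelial markers went both ways, with 3 higher and 5 lower of 12, and fry did not pass (adjusted p = 0.254). Angiogenesis genes were higher at 7 and lower at 4 of 30 (fry adjusted p = 0.445).

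Hypoxia response genes were lower at 8 and higher at 5 of 24 (9 and 5 adjusted over the list alone; fry adjusted p = 0.00335; camera adjusted p = 0.964, and adjusted p = 0.999 with an estimated correlation), among them the glycolytic enzyme Pgk1, at 7.79 ± 0.891 CPM in CAST and 22.03 ± 1.35 CPM in WSB, and the transcription factor Epas1, at 141 ± 3.56 and 184 ± 10.2 CPM (SD, n = 6 each). Pgk1 shares 58.7% of its sampled 32-mers with other genes. Of 29 cell death genes, 7 were higher and 6 lower (fry adjusted p = 0.0287; camera adjusted p = 0.964, and adjusted p = 0.999 with an estimated correlation). Pmaip1, which encodes the apoptosis promoter Noxa, was at 15.8 ± 2.04 and 2.96 ± 0.807 CPM, and Casp12 at 2.78 ± 1.57 and 0.451 ± 0.133 CPM. The fry call of this list was lost without CAST_170, CAST_201, WSB_138 or WSB_147, with adjusted p of 0.0595 to 0.0846. Complement genes were split, 5 higher and 6 lower of 17, with C4b, which shares 45.3% of its sampled 32-mers with other genes, at 18.7 ± 3.86 and 5.40 ± 0.661 CPM.

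None of 8 pan-neuronal and none of 12 excitatory markers was called, although 2 of the 8 were lower with CAST_142 and WSB_100 left out, and Snap25, a synaptic vesicle fusion protein, was at 2069.5 ± 193 CPM in CAST and 2293 ± 272 CPM in WSB (SD, n = 6 each; adjusted p = 0.183 by edgeR). Of 11 inhibitory markers, Npy, Sst and Cck were lower in CAST (fry adjusted p = 0.00958; camera adjusted p = 0.964, and adjusted p = 0.999 with an estimated correlation), Npy at 34.5 ± 8.58 against 55.6 ± 7.56 CPM. Of 18 ionotropic glutamate receptor genes, 2 were higher and 2 lower (2 and 0 adjusted over the list alone; fry adjusted p = 0.606), and with CAST_142 and WSB_100 left out 5 were higher and 1 lower (fry adjusted p = 0.00562; camera adjusted p = 0.965, and adjusted p = 0.983 with an estimated correlation). Of 14 GABA-A receptor genes only Gabrb1 was called (none adjusted over the list alone), with an adjusted p of 0.04996 that rose to 0.0508 to 0.0609 under the other scalings. Of 9 tested sex-linked transcripts only Tsix was called, higher in CAST (list fry adjusted p = 0.00958; camera adjusted p = 0.964, and adjusted p = 0.999 with an estimated correlation). Only 3.19% of the Tsix body lies outside other genes, so its count is uncertain. Over the 42 lists, camera called 0 and fry called 8, and fry called 12 with CAST_142 and WSB_100 left out. Those added were the leukocyte, ionotropic glutamate receptor, metabotropic glutamate receptor and glucocorticoid target lists, and camera again called 0, with the preset and with an estimated correlation.

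Calls were spread over all chromosomes. The share called was lower than elsewhere on chromosome X (34.3%; Fisher's exact test, adjusted p = 2.1e-04) and chromosome 15 (37.5%, adjusted p = 0.0284) and higher on chromosome 13 (49.5%, adjusted p = 0.00126). Among calls of at least 2-fold, chromosome 13 (17.2%, adjusted p = 0.00105) and chromosome 1 (15.04%, adjusted p = 0.0189) held more and chromosome 11 fewer (9.47%, adjusted p = 0.0117), while X (adjusted p = 0.132) and 15 (adjusted p = 0.0735) did not pass.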

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

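The tests of the loss of CAST reads, of Tmtc2 and Jarid2 and of CAST_142 were chosen after the values were seen; the tests of shared sequence and of other splits were set beforehand. Each library measure, list score and named gene was searched, within each strain, for an animal whose gap to its nearest neighbour was large for the range of the 6 (Dixon's test). Of 344 groups searched 42 had such an animal, where chance gives about 1 in 20. CAST_142 accounted for 17 of them, and WSB_100 and WSB_120 for 7 each.

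CAST_142 held the highest cerebellum list score, 6.75 (mean log2 CPM), and the lowest striatum score, 3.64. Its Cbln3 was at 344 CPM, Ppp1r17 at 68.1, Il16 at 60.8 and Gria4 at 519 CPM, all above the other CAST animals. Its striatum score lay below the lowest of the other 11 animals by a difference of -2.19, but these levels are what raised the question of other brain parts in the sample and cannot also test it. A WSB library under a CAST label would hold reads of genes restricted to WSB. Of 20 such genes, chosen with CAST_142 left out, 0 (0%) had at least 10 reads in it and 19 had none, which argues against such a swap. Other brain parts in the tissue may account for CAST_142 and stay open, and no biological explanation was tested because the labels give no dissection.

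Other values of CAST_142 that stood apart were the list scores of microglia (3.35), ionotropic glutamate receptors (7.26) and glucocorticoid targets (4.87). Kcnmb3 (29.3 CPM), Ly6a (3.14 CPM), Sult1a1 (8.61 CPM) and Casp12 (5.96 CPM) were higher in it, and Cacna1h (59.7 CPM), Wfs1 (125.0 CPM), Rarres2 (4.83 CPM) and C1qc (8.61 CPM) were lower. WSB_120 had a cerebellum score of 3.05, Cbln3 at 9.26 CPM, a heat shock score of 6.32 and Hspa1b at 38.1 CPM, with Wfs1 at 179.7, Aldh1l1 at 50.8 and Tjp1 at 172.8 CPM. WSB_100 had Doc2g at 13.8, Cacna1h at 181.3, Tlr4 at 3.07, Trim43b at 0.230, Sult3a1 at 0.333, Fam213b at 19.6 and Kdr at 15.9 CPM. Of the remaining libraries, CAST_170 stood apart for Fam213b (0.0638 CPM), Cwc22 (19.4 CPM) and Hbb-bt (30.4 CPM), CAST_201 for Nr3c1 (167.1 CPM) and CAST_202 for Fgfr3 (151.7 CPM). WSB_138 did so for Srebf2 (281.8 CPM), Cry2 (76.3 CPM) and Cox7a2 (103.9 CPM), WSB_169 for Zfp738 (0 CPM) and Clic4 (84.7 CPM), and WSB_135 for Ap2m1 (57.2 CPM). Of these genes, Doc2g, Hspa1b, Hbb-bt, Ly6a, Trim43b, Cwc22 and Ap2m1 share 27.3% to 71.3% of their sampled 32-mers with other genes.

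Large strain differences were concentrated in genes with close copies. Of 494 genes called with at least an 8-fold difference, 32.6% were pseudogenes. Genes that share at least 20% of their 32-mers with another gene reached that size in 221 of 2026 cases against 273 of 16370 of the rest (odds ratio 7.22, Fisher's exact test p = 1.17e-83), and among protein-coding genes alone the odds ratio was 6.72. Loss of CAST reads that differ from the reference should push such differences towards lower counts in CAST. Only 47.2% (233 genes) were lower, which argues against plain loss as the main source. CAST reads that aligned to another copy instead would raise its count, so direction cannot speak to them. Reads moved between copies may thus account for part of these differences, and copy number or expression differences between the strains stay open, untested.

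Tmtc2 in WSB and Jarid2 in CAST varied among animals of a strain along with the ribosomal-RNA-type gene CT010467.1. Pearson's r was 0.92 for Tmtc2 over the 6 WSB libraries (exact permutation p = 0.0097, adjusted p = 0.0156) and 0.99 for Jarid2 over the 6 CAST libraries (exact permutation p = 0.0056, adjusted p = 0.0139; rho = 0.83, exact permutation p = 0.0583, adjusted p = 0.0667; r = 0.95 without CAST_201 and CAST_200); in WSB, Jarid2 had r = 0.79 (exact permutation p = 0.0528, adjusted p = 0.0603; r = 0.97 without WSB_169 and WSB_147) and rho = 0.94 (exact permutation p = 0.0167, adjusted p = 0.0222). Jarid2 was at 1461 ± 897 CPM in CAST and 94.9 ± 19.6 CPM in WSB (SD, n = 6 each). A candidate source is ribosomal RNA reads counted in these genes, for Jarid2 in both strains. Higher Tmtc2 transcription in WSB alone cannot be told apart from it by spread: the coefficient of variation of Tmtc2 among WSB animals was 51.1%, against a median of 7.30% in 88 genes of like level, and its percentile among them, 98.9, fell between the bounds set. With 88 genes the upper bound could be passed only by a spread above that of every one of them, so this outcome rests on a coarse scale.

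Other splits of the 12 animals did not reach the gene calls: the real split called 7866 genes, and the highest of 99 others called 8. Thus 1 of 100 splits gave as many. Every other split mixes the strains in both groups, so the strain difference enters its spread between animals. Its calls therefore do not show how many would arise without a strain difference. For lists called by fry the real split gave 8 and the highest other 5, so again 1 of 100 gave as many. Fry tests a list for change and does not compare it with other genes. With 7866 genes called in the real split and at most 8 in the others, this says nothing of these lists in particular. Camera called 0 lists in the real split, so that 100 of 100 splits gave at least as many was fixed in advance and tests nothing. Almost all other splits called lists by camera, up to 18, although their median number of called genes was 0. Camera with the preset correlation can thus call these lists where no genes are called. This also limits its call of the interferon-stimulated genes with no filter. Differences among the samples other than strain, such as the tissue of CAST_142, may give the 18 lists, and this was not tested further.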

How the results depend on the processing

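The alternatives that left out CAST_142 and WSB_100 together, or kept only some genes, were chosen after seeing the data; the others were fixed beforehand. The 7866 calls stayed within 1.5 times under all alternatives fixed beforehand except a test against a fold of 1.5, which called 2344 because it asks for a larger change. Kept to genes with their own sequence and body, 5090 were called of 12811 tested. Leaving out each animal gave 7313 to 8726 calls, and 323 to 733 of the main calls were lost, none with a change of sign. Calls of at least 2-fold numbered 2249, and 3716 with DESeq2, 3971 with no filter, 1262 with at least 1 CPM in 6 animals and 1185 in genes with their own sequence and body; leaving out each animal gave 2341 to 2414. The filters change how many weakly expressed genes enter; for DESeq2 the cause was not tested. Camera called 0 of 42 lists (2 at an unadjusted p under 0.05), 0 with an estimated correlation and 0 to 0 without each animal, but 1, the interferon-stimulated genes, with no filter; fry called 8, and 12 without CAST_142 and WSB_100. Strain-restricted genes numbered 35, and 60 with at least 5 reads, 17 with at least 20, 155 with up to 2 reads allowed in the low strain (88 CAST, 67 WSB), and 36 to 50 without each animal; without WSB_100 the 16 of CAST became 27. Of 2454 values of 123 named genes under alternatives, 2344 kept direction and side of the threshold, 105 lost the call (18 genes) and 5 changed direction (2 genes). Pde10a, never called, was -0.20 to 0.045 on the log2 scale without each animal (0.0021 without CAST_202) and 0.053 without CAST_142 and WSB_100; Slc17a6, also not called, was -0.12 to 0.43 and -0.10. Cbln3 lost its call without those 2 animals (log2 change 0.35, adjusted p = 0.844). Lane agreement, the chromosome count and the first component kept their sides: medians of 1.12 and 1.13, 3 chromosomes each (1 shared), and 71.1% to 88.8% of variance. No paired analysis was possible because the strains share no animal number. Depth limits genes near the floor of 3 reads and genes listed at 0.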

Other observations

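The tests named here were chosen after the values were seen, except the gene lists, which were fixed beforehand. Several gene groups not described above went both ways. Of 32 antioxidant genes, 10 were higher and 8 lower in CAST (10 and 10 adjusted over the list alone), with the extracellular superoxide dismutase Sod3 at 5.95 ± 0.953 CPM in CAST and 2.80 ± 0.353 CPM in WSB and the glutathione transferase Gsta4 at 6.01 ± 1.99 and 23.2 ± 3.08 CPM (SD, n = 6 each). Slc7a11, the cystine-glutamate exchanger, was at 55.1 ± 7.01 and 30.65 ± 4.65 CPM. Of 18 antigen presentation genes, 6 were higher and 4 lower, with the class I genes H2-K1 at 2.102 ± 0.102 and 5.69 ± 0.497 CPM and H2-D1 at 4.10 ± 0.364 and 1.78 ± 0.308 CPM; these share 20.7% and 30% of their 32-mers with other genes. Among the angiogenesis genes were Cxcl12 at 121 ± 19.3 and 73.4 ± 10.5 CPM and Clic4, a chloride channel protein linked to collateral vessel formation, at 67.4 ± 4.59 and 96.7 ± 6.32 CPM.

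Of 11 astrocyte markers, 3 were higher, among them Gja1 at 243 ± 19.7 and 176 ± 15.04 CPM and Fgfr3 at 136 ± 8.08 and 101 ± 6.04 CPM, and Aldh1l1 was lower. Of 8 oligodendrocyte precursor markers, Olig1, Olig2 and Vcan were higher. Of 12 oligodendrocyte markers, Cldn11 alone was called, lower in CAST; none was called adjusted over the list alone, and 3 were lower with CAST_142 and WSB_100 left out. Immediate early genes were called higher at 2 of 20, Npas4 and Nr4a1, and at 0 adjusted over the list alone. With CAST_142 and WSB_100 left out, 1 was higher.

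Y-linked transcripts were at 3 levels. Ddx3y was at 61.8 to 83.7 CPM in CAST_142, CAST_202, CAST_203, WSB_100, WSB_138 and WSB_169, at 0.0540 to 0.285 CPM in CAST_200, CAST_201 and WSB_135, and at 3.19, 2.50 and 2.40 CPM in CAST_170, WSB_120 and WSB_147. Kdm5d, Uty and Eif2s3y were high, low and very low in the same libraries. These libraries are not treated as groups here, and sex is not given in the labels. In the order of the library indexes, CAST_170, WSB_120 and WSB_147 directly follow CAST_142, WSB_100 and WSB_138, which are high. In CAST_170, Cbln3 (11.9 CPM) and Gabra6 (11.5 CPM), which are not Y-linked, were second only to CAST_142 (344 and 333 CPM). WSB_120 came next for both (9.26 and 6.58 CPM), although WSB_100 before it was low (0.256 and 0.051 CPM). Mixing of reads between libraries was not tested, so the middle level may not be one of expression.

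Gm26561, a long noncoding gene, was at 2170 ± 1191 CPM in CAST and 155 ± 81.9 CPM in WSB and rose with CT010467.1 within both strains (Pearson r = 0.99 over 6 CAST libraries, exact permutation p = 0.0042, adjusted p = 0.0139; r = 0.96 over 6 WSB libraries, exact permutation p = 0.0069, adjusted p = 0.0139; rho = 0.94 in each, exact permutation p = 0.0167, adjusted p = 0.0222). Without the 2 libraries farthest from the median, r was 0.97 in CAST and 0.98 in WSB. D130009I18Rik also rose with it in both strains (r = 0.97 over 6 CAST libraries, exact permutation p = 0.0042, adjusted p = 0.0139, and 0.81 without CAST_201 and CAST_200; r = 0.85 over 6 WSB libraries, exact permutation p = 0.0333, adjusted p = 0.0444, and 0.997 without WSB_169 and WSB_147; rho = 0.94 in each, exact permutation p = 0.0167, adjusted p = 0.0222). Sfi1, a centrosome gene, and its neighbour Pisd-ps1 were at 444 ± 36.3 and 505 ± 73.6 CPM in CAST against 76.2 ± 7.57 and 53.3 ± 9.28 CPM in WSB; both lie on chromosome 11 and were chosen after their values were seen, and copy number was not analysed here.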
